A study of Homo sapiens with 6 samples.

How the data were processed

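Total RNA of whole lung homogenates from 3 lungs with idiopathic pulmonary fibrosis (IPF, a scarring disease of the lung of unknown cause) and 3 control lungs was measured on 6 single-colour Affymetrix arrays, 1 array per sample. Per the labels, RNA was extracted with Trizol and biotin-labelled cRNA was made from 0.5 ug of it. The deposited table holds 1 log2 value per probe set and array. RMA (robust multi-array average, which corrects background, normalizes arrays to each other and summarises the probes of a probe set on a log2 scale) is the only tool named in the submitters' processing notes, and its version is not given in the sources used here. The table itself does not state its log base. Its values, from 2.21 to 13.59, lie in the range of RMA output on the log2 scale and were used as such, without further transformation. The array medians were 6.49, 6.50 and 6.49 in control replicates 1 to 3 and 6.67, 6.59 and 6.64 in IPF replicates 1 to 3. Scanner intensities and detection calls were not used here, so background correction could not be varied and a dim probe set could not be separated from background. The number of arrays limits the precision. No slide or scan date was used, so array batches were not tested.

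Groups and replicate numbers came from the labels' sample titles. The labels call the lungs replicates without saying more on their origin, so p-values measure only the spread between these samples. No 2 arrays held the same values, the smallest of the largest differences within a pair being 2.21 on the log2 scale. All 1259 probe sets of the table were tested. A probe set was named through the RefSeq accession in its identifier, without version, matched to a table of human genes of the GRCh38.p14 assembly. This gave 1043 probe sets with 1 gene (927 genes, 93 of them with more than 1 probe set) and left 216 unnamed, of which 189 carry UCSC identifiers, 26 RefSeq identifiers and 1 another kind. No genome build is given in the sources used here, so no coordinates are printed. The brightest probe set by its mean over all 6 arrays stands for a gene. Of the probe sets, 353 carry a suffix (s or x) that marks probes shared between transcripts or sequences.

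IPF and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided), with Benjamini-Hochberg adjustment over all 1259 probe sets and a threshold of 0.05 on the adjusted p. The moderated test had 6.05 degrees of freedom, 2.05 of them from the prior. "Rose" and "fell" are used only for probe sets past that threshold. For single genes an exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1. In data simulated from this table's spread for this comparison (1259 probe sets, 200 of them changed, 10 simulations) the test called 60.4% of probe sets changed by 0.5 on the log2 scale, 91.0% of those changed by 1 and 98.0% of those changed by 2, and 3.86% of its calls were probe sets that had not been changed. The simulated list test found 10 of 10 lists shifted by 0.4 and 0 of 10 unshifted ones. Both simulations drew probe sets independently, and the list test used an unadjusted p under 0.05. Estimated correlations within the measured lists ran from -0.08 (hyaluronan) to 0.52 (macrophage markers), so these rates may not hold for the measured data.

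Gene lists for glycan pathways, signalling families and cell types (33 in all, 26 of them with at least 5 measured genes) were fixed before the data were examined, as were the main test, the named genes and the alternatives, apart from those said to be added. Of the lists, 4 follow the study's stated aims, namely heparan sulfate synthesis and the TGF-beta, FGF and Wnt pathways. Each list of at least 5 measured genes was tested against the other genes with camera (preset correlation between genes 0.01) and with camera using an estimated correlation. Each was also tested with fry, which does not set a list against other genes. For each test the p-values were adjusted over the 26 lists. The shift of a list is the mean log2 change of its members minus that of the other genes, and the mean change of all genes was 0.10. For each list the count of members past the test is given over all probe sets and adjusted over the list alone.

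Named genes are SULF1 and SULF2, the 10 genes with the largest rise and the 10 with the largest fall past the threshold, and up to 3 members of each list with the smallest p (2 for lists of under 10 measured members), whether or not they passed. A gene that falls under more than 1 part of the rule is named under each. Genes whose probe sets name several genes were not to be named, and XIST and Y-linked genes were left out. Genes outside this rule are said to be chosen after their values were seen. For 1 of the genes past the test, which the counts include, neither name nor values are reported here.

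Alternatives were the replicate number as a block, each array left out in turn, an intensity trend or robust fit in eBayes, array weights, quantile normalization of the deposited values, centring each array on its median or on the mean of 3 housekeeping genes (RPL13A, GUSB and LDHA), leaving out the dimmest 25% or 50% of the probe sets, other thresholds, a test without moderation, the mean of a gene's probe sets, and the other list tests. Counts of list members without control replicate 2 or control replicate 3 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.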

Results

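RNA of 3 IPF lungs and 3 control lungs was measured on arrays, and the deposited table holds 1259 probe sets. Whether these are all probe sets of the array is not known, so rankings and list tests are relative to the genes of this table. The probe sets name 927 genes, of which 500 are in at least 1 of the gene lists for glycan synthesis and breakdown, lectins, growth factor and chemokine signalling, and cell types. The study asked how SULF1 and SULF2 and other glycan-related genes, among them the enzymes that build heparan sulfate and the components of the TGF-beta, FGF and Wnt pathways, are expressed in IPF compared with normal lung. Arrays of the same group correlated across probe sets at 0.979 to 0.991 and arrays of different groups at 0.963 to 0.976. The first principal component, with 53.3% of the variance, had scores of -10.84 to -7.56 in the controls and 6.62 to 10.82 in IPF. On the second, with 21.1%, control replicate 2 stood apart at -9.94.

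Of the 10 genes with the largest rise in IPF lungs 5 were chemokines, beside SULF1, 2 growth factors or cytokines (IGF1 and GDF15), the mucin MUC5B and UGT1A1, and the genes with the largest fall included a lymphatic growth factor and several glycosyltransferases. CXCL14, a chemokine of epithelia and fibroblasts, had the largest rise at 11.9-fold (log2 change 3.58, SE 0.50), and IGF1, a growth factor, rose 5.49-fold. The neutrophil-attracting CXCL6 had a log2 change of 2.93 (SE 0.44), but its control level of 3.37 may be background, so the size of its rise is uncertain. VEGFD, a growth factor for lymphatic vessels, had the largest fall, from 9.63 ± 0.22 to 7.59 ± 0.26 (SD, n = 3), and was 4.11-fold lower. FGF12, an intracellular member of the FGF family, was 3.65-fold lower and CLEC3B (tetranectin, a plasminogen-binding lectin) 3.26-fold lower. UGT1A1, a glucuronosyltransferase whose probe set can detect other genes of the UGT1A cluster that share its last exons, was 3.87-fold higher.

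In total 145 of 1259 probe sets passed limma's test at an adjusted p under 0.05, 93 of them higher in IPF and 52 lower. These were 112 genes by their brightest probe set, 77 higher and 35 lower, and 23 of the 145 probe sets had no gene name. At an unadjusted p under 0.05 there were 362. Of 13 genes with several probe sets and at least 1 past the test, all probe sets passed in 3, and the signs were opposite in 1, the interferon receptor IFNAR2. In 449 probe sets (35.7%) the 3 IPF values lay wholly above or below the 3 control values, which chance gives for 10%. The share of calls that were higher, 64.1%, depended on the scaling: 59 were higher and 64 lower after a further quantile normalization, 43 higher and 72 lower with each array centred on its median, and 29 higher and 198 lower with arrays centred on 3 housekeeping genes. Median centring moved the median log2 change of all probe sets by -0.14 and housekeeping centring by -0.36, so a small rise is a rise relative to the array as deposited, and its sign is not fixed. The 3 housekeeping genes were themselves higher in IPF (LDHA by 0.48 and past the test, RPL13A by 0.43 and GUSB by 0.15). Centring on them therefore lowers every log2 change, and whether they are a stable reference was not tested. Of the 145 probe sets, 142 kept their direction with housekeeping centring and all 145 with the other 2 scalings. Fewer of the 145 still passed the test, 81 with housekeeping centring, 95 with median centring and 108 with the further quantile normalization. The count fell to 58, 50 and 9 without control replicates 1, 2 and 3, and to 54, 28 and 98 without IPF replicates 1, 2 and 3. The 9 probe sets that passed without control replicate 3 were MGAT2, CCL11, VCAN, VEGFD, SULF1, FUT8, CXCL12, HS6ST2 and IGF1, and these were also the 9 that passed in all 6 fits that each left out 1 array.

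**Figure D1:**
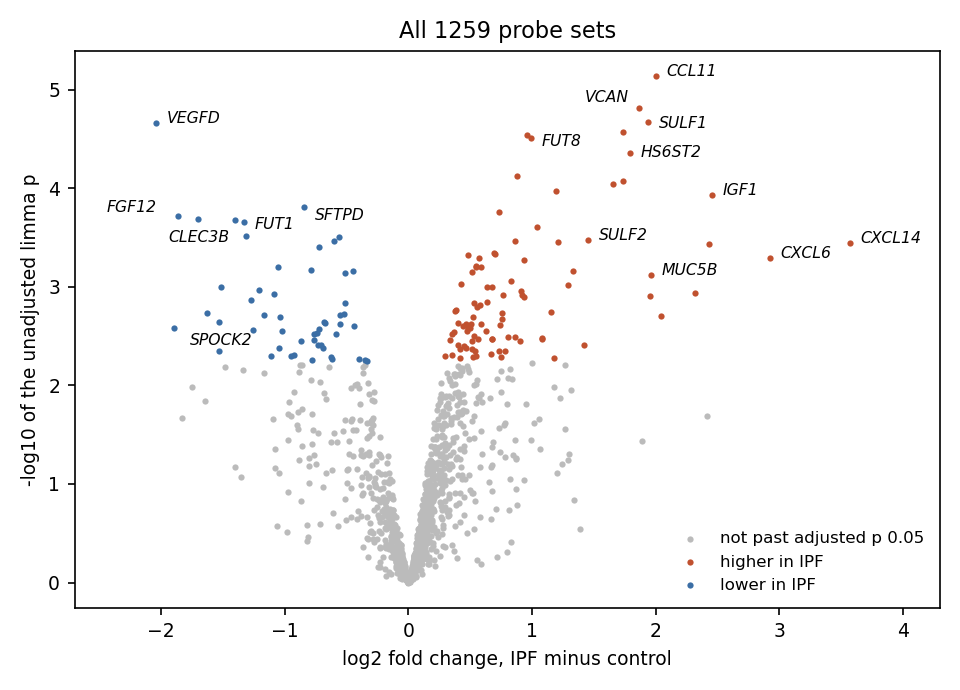
Log2 change between IPF and control (horizontal axis) against -log10 of limma's unadjusted p (vertical axis), 1 point per probe set. Points past an adjusted p of 0.05 are coloured, 93 higher in IPF (29 with arrays centred on housekeeping genes) and 52 lower, with CXCL14 farthest right at 3.58 and VEGFD farthest left among the coloured points at -2.04.

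Both extracellular heparan sulfate 6-O-endosulfatases, the enzymes that remove 6-O-sulfate groups from finished heparan sulfate chains, rose in IPF. SULF1 went from 5.74 ± 0.31 to 7.68 ± 0.07 on the log2 scale (SD, n = 3 per group), a 3.83-fold rise (log2 change 1.94, SE 0.16, limma adjusted p = 0.0056). SULF2 went from 7.48 ± 0.25 to 8.94 ± 0.32, a 2.74-fold rise (log2 change 1.46, SE 0.20, limma adjusted p = 0.0167). Each was higher in all 3 IPF arrays than in all 3 controls, which is the smallest exact two-sided permutation p that 3 against 3 can give, 0.1. HPSE, the heparanase that cleaves heparan sulfate chains, had a log2 change of 0.84 (SE 0.22, limma adjusted p = 0.0621) and its relative HPSE2 one of 0.33 (SE 0.15, limma adjusted p = 0.209); both were named after their values were seen. Of these 4 remodelling genes 2 rose over all probe sets and 3 adjusted over the list alone, and the study named SULF1 and SULF2 in its title, so that count is not independent of its choice. SULF1 passed without each array in turn. SULF2 did not pass without control replicate 3 (log2 change 1.36, limma adjusted p = 0.0756) or IPF replicate 2 (1.38, limma adjusted p = 0.0521).

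**Figure D2:**
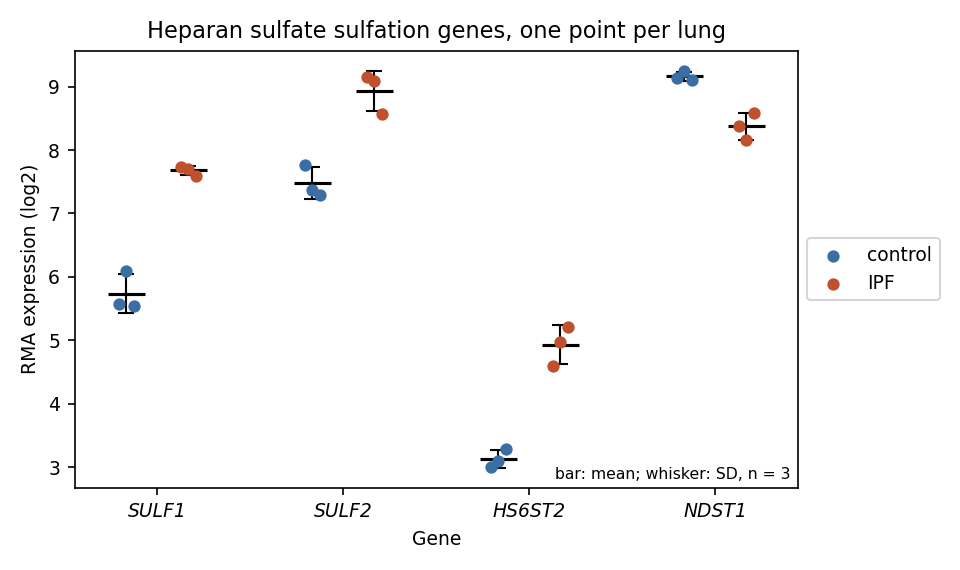
RMA expression on the log2 scale (vertical axis) of SULF1, SULF2, HS6ST2 and NDST1, with 1 point per lung, the mean as a bar and the SD as a whisker (n = 3). The IPF points of SULF1, SULF2 and HS6ST2 lie above all control points and those of NDST1 below them.

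Among the enzymes that build and sulfate heparan sulfate chains, 1 of 26 measured rose and 1 fell. HS6ST2, a 6-O-sulfotransferase that adds the sulfate the SULF enzymes remove, went from 3.14 ± 0.15 to 4.93 ± 0.31 (SD, n = 3; log2 change 1.79, SE 0.17, limma adjusted p = 0.00687). It was dim, at the 10.7th percentile of mean brightness, so its fold rests on control values that may be background. NDST1, the main N-deacetylase and N-sulfotransferase of most tissues, fell by 0.79 from 9.16 ± 0.07 to 8.37 ± 0.21 (SE 0.12, limma adjusted p = 0.0209). HS3ST5, a 3-O-sulfotransferase, had a log2 change of -0.28 and did not pass (limma adjusted p = 0.0751). The counts adjusted over the list alone were also 1 and 1, and the list as a whole did not pass camera (adjusted p = 0.86). Of the 6 fits that each left out 1 array, HS6ST2 passed in 6 and NDST1 in 1, and without control replicate 2 or 3 NDST1 did not pass; with housekeeping centring 1 rose and 4 fell. Of 11 heparan sulfate proteoglycan cores, GPC1 (a glypican, anchored to the membrane by lipid) rose by 0.41 (SE 0.09) and GPC3, another glypican, fell by 0.78 (SE 0.19), with the same counts adjusted over the list alone. GPC1 did not pass with housekeeping centring (0.06), median centring (0.28) or the further quantile normalization (0.32). It passed in 0 of the 6 fits that each left out 1 array, and neither glypican passed without control replicate 2 or 3. The basement membrane proteoglycan HSPG2 (perlecan) had a log2 change of 0.44 (limma adjusted p = 0.226), and this list did not pass camera either (adjusted p = 0.411).

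The TGF-beta family, central to fibrosis, had 37 measured members, of which 5 rose and 1 fell, or 7 and 2 adjusted over the list alone. GDF15, a stress-induced cytokine distantly related to TGF-beta, rose 4.11-fold (log2 change 2.04, SE 0.39, limma adjusted p = 0.0333). GDF11 rose by 0.59 (SE 0.09) and the secreted BMP antagonist CHRD (chordin) by 0.55 (SE 0.08). BMP8A at 0.64 and the type I receptor ACVR1 at 0.53 also rose, both named after their values were seen. ACVRL1, a type I receptor found mainly in endothelium, fell by 1.21 (SE 0.21, limma adjusted p = 0.026), and the list of endothelial markers that includes it was lower too (shift -0.42, camera adjusted p = 0.0187), a call lost with an estimated correlation (adjusted p = 0.614 with an estimated correlation) and with housekeeping centring (camera adjusted p = 0.231). The TGF-beta list did not pass camera (adjusted p = 0.86; median change 0.05, mean 0.10, camera direction down). Without control replicate 3 no member passed and without control replicate 2 the same number rose, 5, and 0 fell; with housekeeping centring 1 rose and 8 fell.

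In the FGF pathway 1 of 26 measured members rose and 2 fell, with the same counts adjusted over the list alone. FGF12 fell by 1.87 (SE 0.23, limma adjusted p = 0.0148) and the receptor FGFR4 by 0.70 (SE 0.16, limma adjusted p = 0.042), while FGF11, like FGF12 an intracellular family member, rose by 0.74 (SE 0.15, limma adjusted p = 0.0358). In the Wnt pathway 1 of 29 rose and 3 fell, again the same adjusted over the list alone. The ligand WNT10A rose by 0.68 (SE 0.11), the ligand WNT7A fell by 0.45 (SE 0.07) and the receptor FZD8 fell by 1.26 (SE 0.26). A related receptor, FZD5, fell by 1.02 (SE 0.21) and was named after its values were seen. Neither list passed camera (adjusted p = 0.194 for FGF and 0.427 for Wnt), and in both the median and the camera direction differed in sign. No member of either list passed without control replicate 3; without control replicate 2, 1 FGF member and 0 Wnt members fell and none rose. With housekeeping centring 0 FGF members rose and 6 fell, and 0 Wnt members rose and 8 fell.

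Genes that build chondroitin and dermatan sulfate, the other sulfated chains of matrix proteoglycans, were higher in IPF as a list. Of 15 measured, 4 rose and 0 fell, 8 and 0 adjusted over the list alone, and 14 had a positive log2 change. CHST15, which makes the doubly sulfated chondroitin sulfate E unit, rose by 0.76 (SE 0.14), CSGALNACT2, which adds the first chain sugar, by 0.64 (SE 0.11) and the polymerizing factor CHPF2 by 0.37 (SE 0.08). CHSY3, a chain polymerase named after its values were seen, rose by 0.67 in 1 of its 2 probe sets. The list's shift was 0.30 (camera adjusted p = 0.0333), and the call was lost with an estimated correlation (adjusted p = 0.659 with an estimated correlation). It was also lost without control replicate 3 (0.28, camera adjusted p = 0.0517), IPF replicate 1 (0.25, camera adjusted p = 0.0917) or IPF replicate 3 (0.34, camera adjusted p = 0.0575). The median change was 0.37 as deposited and 0.02 with housekeeping centring, which takes the same amount from every gene; 0 members passed there, but the list kept its call (camera adjusted p = 0.00557). By member, 1 passed without control replicate 2 and 0 without control replicate 3. In the same lungs all 4 measured fibroblast markers had a positive log2 change as deposited, their median being 0.48 and, with housekeeping centring, 0.13.

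Proteoglycan cores other than those of heparan sulfate were also often higher, with 6 of 19 measured past the test upward and 1 downward, or 7 and 1 adjusted over the list alone, though the median of the list was 0.28 as deposited and -0.07 with housekeeping centring, where 4 rose and 1 fell. VCAN (versican, a large chondroitin sulfate proteoglycan of provisional matrix) went from 8.96 ± 0.17 to 10.83 ± 0.23 (SD, n = 3), a 3.65-fold rise (limma adjusted p = 0.0056). OGN (osteoglycin, a small leucine-rich protein) rose 3.34-fold and SPOCK1 (testican-1) 2.32-fold, while SPOCK2 (testican-2) was 2.89-fold lower, from 10.45 ± 0.21 to 8.92 ± 0.60. LUM (lumican), also a fibroblast marker, rose 1.91-fold. The list did not pass camera (adjusted p = 0.149); 4 members rose without control replicate 2, and VCAN was the only one past the test without control replicate 3. Of 9 hyaluronan genes 2 fell and 0 rose, 3 and 0 adjusted over the list alone, namely the hyaluronidases HYAL1 (fell by 1.31, SE 0.18) and HYAL2 (fell by 1.11, SE 0.26); the list did not pass camera (adjusted p = 0.411; median 0.08, mean -0.11), and 1 fell without control replicate 2 and 0 without control replicate 3. Among 15 genes of keratan sulfate and related sulfation 3 rose and 1 fell, the same adjusted over the list alone. B4GALT4, a galactosyltransferase, rose by 0.48 and the sulfotransferase CHST6 by 0.68, and CHST1, another keratan sulfate sulfotransferase, fell by 0.44. That list did not pass camera (adjusted p = 0.821; median 0.07, camera direction down), 0 rose and 0 fell without control replicate 2 or 3, and with housekeeping centring 0 rose and 2 fell.

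Several enzymes that finish protein-linked glycans changed, with members going both ways. FUT8, the only enzyme that adds core fucose to N-glycans, rose from 6.63 ± 0.08 to 7.62 ± 0.10 (SD, n = 3; 1.99-fold, limma adjusted p = 0.0056), and FUT2, which makes the H antigen of mucosal secretions and is an airway marker here, rose by 0.74 (SE 0.09). FUT1, which makes the same structure in other cells, fell by 1.33 (SE 0.17); of 11 fucosyltransferases 2 rose and 1 fell, also adjusted over the list alone, and with housekeeping centring 1 rose and 1 fell. MGAT2, needed for complex N-glycans, rose 1.95-fold (SE of the log2 change 0.09, limma adjusted p = 0.0056) and the trimming mannosidases MAN1A1 and MAN1A2 rose by 0.77 and 0.34. Thus 3 of 18 N-glycan genes rose and 0 fell, 4 and 0 adjusted over the list alone, but with housekeeping centring 1 rose and 3 fell and MAN1A2 was at -0.01. Of 20 sialyltransferases 1 rose and 2 fell, 2 and 2 adjusted over the list alone, and 1 and 8 with housekeeping centring. ST6GAL1, which adds alpha-2,6 sialic acid to N-glycans, rose by 0.92 (SE 0.16), ST6GALNAC5, a ganglioside sialyltransferase, fell by 1.63 (SE 0.31) and ST8SIA6 fell by 0.62 (SE 0.15) to 3.21, a dim level that may be background, so the size of its fall is uncertain. None of these 3 lists passed camera (adjusted p = 0.411, 0.534 and 0.228 in the order named). Without control replicate 3 only FUT8 and MGAT2 passed. Without control replicate 2, 2 fucosyltransferases rose and 1 fell, 1 N-glycan gene rose and 0 sialyltransferases passed.

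MUC5B, the secreted airway mucin, rose 3.89-fold, from 5.64 ± 0.13 to 7.60 ± 0.64 (SD, n = 3; limma adjusted p = 0.0214), and MUC15, a membrane mucin, was 2.41-fold lower, ending at 4.15 ± 0.05, a dim level that may be background, so the size of its fall is uncertain. They were the 2 of 14 mucin genes past the test, 1 up and 1 down, the same adjusted over the list alone; MUC13 had a log2 change of 0.26 as deposited (limma adjusted p = 0.101) and -0.09 with housekeeping centring. Among 24 genes that start and branch mucin-type O-glycans 3 rose and 2 fell, 5 and 2 adjusted over the list alone, and 0 and 3 with housekeeping centring. GALNT1, which adds the first sugar, rose by 0.55 (SE 0.08), GALNT18, of the same family, fell by 1.40 (SE 0.18), and GCNT2, which makes the branched I antigen, fell by 1.04 (SE 0.20). Neither list passed camera (adjusted p = 0.534 for mucins and 0.609 for O-glycans). No member of either passed without control replicate 3, and 1 of each list, both lower, passed without control replicate 2. All 4 measured airway markers, among them MUC5B and FUT2, had a positive log2 change, with median 0.82.

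Glycan-binding proteins changed in both directions. Of 44 C-type lectins and selectins 6 rose and 3 fell, 7 and 3 adjusted over the list alone, and 2 and 6 with housekeeping centring. CLEC3B went from 11.70 ± 0.05 to 9.99 ± 0.43 and SFTPD, the surfactant collectin of type II cells, from 12.12 ± 0.15 to 11.28 ± 0.07 (SD, n = 3; limma adjusted p = 0.0148 and 0.0141), whereas CD248 (endosialin, of pericytes and fibroblasts) rose by 1.04 (SE 0.14). Of 13 galectins 1 rose and 0 fell, 2 and 1 adjusted over the list alone, namely LGALS7 by 1.08 (SE 0.23), whose probe set can also detect the near-identical LGALS7B. With quantile normalization or median centring 0 galectins rose and 1 fell, and with housekeeping centring 0 rose and 2 fell. LGALS7 lost its call there but stayed positive (0.73 with housekeeping centring). The abundant LGALS1 was at 0.37 (limma adjusted p = 0.0573) and LGALSL, galectin-like and of no known sugar binding, at -0.86 (limma adjusted p = 0.0524). Of 14 Siglecs, the sialic acid-binding lectins of leukocytes, 1 rose and 0 fell, also adjusted over the list alone: SIGLEC9 at 0.38 (SE 0.07). SIGLEC1 at 0.41 and SIGLEC15 at 0.32 did not pass, and with housekeeping centring no Siglec passed and SIGLEC15 was at -0.04. No list of the 3 passed camera (adjusted p = 0.534, 0.46 and 0.205), with medians of 0.01, -0.04 and 0.28. No member passed without control replicate 3. Without control replicate 2, 3 C-type lectins rose and 2 fell, 0 galectins passed and 1 Siglec other than SIGLEC9 rose. SIGLEC9 passed in 0 of the 6 fits that each left out 1 array.

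Lysosomal enzymes that degrade glycans were higher as a list, 24 of 26 measured having a positive log2 change as deposited, though the median of 0.22 became -0.13 with housekeeping centring and 0 members passed there, where the list's call was lost too (camera adjusted p = 0.231). GUSB, which is among the 3 housekeeping genes, is also a member of this list, so that centring is not independent of it. Over all probe sets 5 rose and 0 fell, 6 and 0 adjusted over the list alone. FUCA1, the lysosomal fucosidase, rose by 0.70 (SE 0.10), ARSB, which removes 4-sulfate from chondroitin and dermatan sulfate, by 0.83 (SE 0.14) and CTSA, the protective protein of sialidase and galactosidase, by 0.52 (SE 0.08). MAN2B1, a lysosomal mannosidase named after its values were seen, rose by 0.51 (SE 0.11). The shift was 0.18 (camera adjusted p = 0.0333), and the call was lost with an estimated correlation (adjusted p = 0.659 with an estimated correlation). The call was kept in 1 of the 6 fits without 1 array, that without control replicate 1 (camera adjusted p = 0.0117), and was otherwise 0.0519 to 0.109, highest without control replicate 3. Without control replicate 2, 1 member passed, and without control replicate 3 none did. In the same lungs 5 of 5 macrophage markers had a positive log2 change as deposited, their median being 0.41 and, with housekeeping centring, 0.06.

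Of 38 chemokines 9 rose and 0 fell, with the same counts adjusted over the list alone. This was the highest count of any list but not the highest share, as 6 of 19 other proteoglycan cores rose. With housekeeping centring 7 chemokines rose, 2 fell and the list's median of 0.28 became -0.07. CXCL12, a stromal chemokine, went from 8.96 ± 0.22 to 10.70 ± 0.20 (SD, n = 3; 3.34-fold, limma adjusted p = 0.0056) in its brightest probe set, and its other 2 probe sets, at 1.23 and 0.37, did not pass. CCL11 (eotaxin-1) rose 4.01-fold, from 4.90 ± 0.25 to 6.90 ± 0.09, the eosinophil and monocyte attractant CCL13 rose 5.40-fold, and CCL19, a chemokine of lymphoid tissue, 4.99-fold. CXCL14 went from 6.20 ± 0.86 to 9.78 ± 0.61, and CXCL6 from 3.37 ± 0.23, a level that may be background, to 6.30 ± 0.89. Camera, which weighs the list against the other genes, did not pass (adjusted p = 0.41). Without control replicate 2, 6 rose, and without control replicate 3 CCL11 and CXCL12 did.

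Of 35 interleukins and their receptors 1 rose and 0 fell, IL2RA at 0.48 (SE 0.10, dim, at the 12.5th percentile, so the size of its rise is uncertain), and 0 passed adjusted over the list alone; IL7R at -1.83 (SE 0.59, limma adjusted p = 0.105) and IL6R at -0.88 (limma adjusted p = 0.0564) did not pass. With housekeeping centring 0 rose and 5 fell, and no member passed without control replicate 2 or 3. Of 27 genes of the VEGF, PDGF, EGF, HGF and insulin-like growth factor families 2 rose and 3 fell, 2 and 4 adjusted over the list alone. IGF1 went from 6.24 ± 0.47 to 8.70 ± 0.34 (SD, n = 3; limma adjusted p = 0.0114), and HGF, a growth factor for epithelium, rose by 0.88 in its brightest probe set, with 2 of its 4 probe sets past the test. VEGFC fell by 0.93 and VEGFA by 0.52, beside VEGFD, so that 3 VEGF ligands fell. Of the 6 fits that each left out 1 array, VEGFD passed in 6, VEGFA in 1 and VEGFC in 0. VEGFA and VEGFC were named after their values were seen. The endothelial marker list was lower in the same lungs (shift -0.42), a call lost with an estimated correlation (adjusted p = 0.614 with an estimated correlation) and with housekeeping centring (camera adjusted p = 0.231). With housekeeping centring 2 rose and 8 fell. IGF1 and VEGFD passed without control replicate 3, and 2 rose and 2 fell without control replicate 2. In the Notch pathway 0 of 13 rose and 3 fell, the same adjusted over the list alone: NOTCH4 by 0.87 and its ligand DLL4 by 0.52, both best known from endothelium, and the Notch-modifying MFNG by 0.55. These 3 lists did not pass camera (adjusted p = 0.41, 0.338 and 0.146), and no Notch member passed without control replicate 2 or 3.

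Endothelial markers were lower in IPF as a list. Of 11 measured 3 fell and 0 rose, the same adjusted over the list alone: ACVRL1, CLEC14A (fell by 1.06, SE 0.16) and ICAM2 (fell by 0.62, SE 0.15). The bright PECAM1 was at -0.19 and CD34 at 0.14, neither past the test; both were named after their values were seen. The shift was -0.42 (camera adjusted p = 0.0187), and the call was lost with an estimated correlation (adjusted p = 0.614 with an estimated correlation). That estimate was -0.04, below the preset 0.01, so correlation between these markers is not what lost the call (unadjusted camera p = 0.0236). The call was also lost without IPF replicate 3 (-0.34, camera adjusted p = 0.0575). With the further quantile normalization (camera adjusted p = 0.0572) or housekeeping centring (camera adjusted p = 0.231) it was lost too. Housekeeping centring takes the same amount from every gene. There the shift stayed at -0.42, 5 markers fell, and the median was -0.65, against -0.30 as deposited. No single marker passed without control replicate 2 or 3. All 4 measured markers of type II alveolar cells had a negative log2 change; SFTPD was the 1 that fell, 2 adjusted over the list alone, and SFTPA1, whose probe set can detect the near-identical SFTPA2, was at -0.97 (limma adjusted p = 0.0997). No type I cell marker was measured. Of 4 airway markers 2 rose, 3 adjusted over the list alone (1 rose with housekeeping centring).

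Macrophage markers had 1 of 5 past the test, COLEC12 at 0.86 (SE 0.12), a scavenger receptor that endothelium also expresses, 2 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.124). With housekeeping centring COLEC12 was at 0.51 and 0 macrophage markers rose. Of 7 neutrophil markers SIGLEC9 rose, 1 also adjusted over the list alone, and SIGLEC5 was at 0.34 as deposited and -0.01 with housekeeping centring (camera adjusted p = 0.433). None of 9 T and NK cell markers (NCAM1 at 0.44, IL7R at -1.83; camera adjusted p = 0.411) or 4 B and plasma cell markers passed, over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05 there were 2 and 2. CXCL13, the B cell attractant of lymphoid follicles, was at 2.42 (SE 0.78, limma adjusted p = 0.103) and CXCR5, its receptor, at 0.22 as deposited and -0.13 with housekeeping centring. Of 4 fibroblast markers LUM rose by 0.94 (SE 0.14), 2 adjusted over the list alone with DCN (decorin) at 0.60. The 3 housekeeping genes were all higher, LDHA past the test at 0.48 (SE 0.10), RPL13A at 0.43 (SE 0.14) and GUSB at 0.15 (SE 0.10), with 1 of 3 past the test and 2 adjusted over the list alone. With control replicate 3 left out no member of these lists passed; without control replicate 2, 2 macrophage, 1 B cell and 0 fibroblast markers rose.

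Of the 26 lists tested, 3 passed camera with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.614. The estimated correlations of these 3 lists were -0.04 (endothelial markers), 0.04 (chondroitin sulfate) and 0.26 (lysosomal degradation). Their unadjusted camera p with these estimates was 0.0236, 0.0673 and 0.292. By fry, which asks only whether a list's own genes move, 8 lists moved on balance one way and 25 moved in either direction. Fry was run only on the values as deposited, where the mean change of all genes was 0.10. It does not take that mean into account, so upward moves may depend on the scaling, which was not tested. In 11 lists the median, the mean and the camera direction differed in sign.

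**Figure D3:**
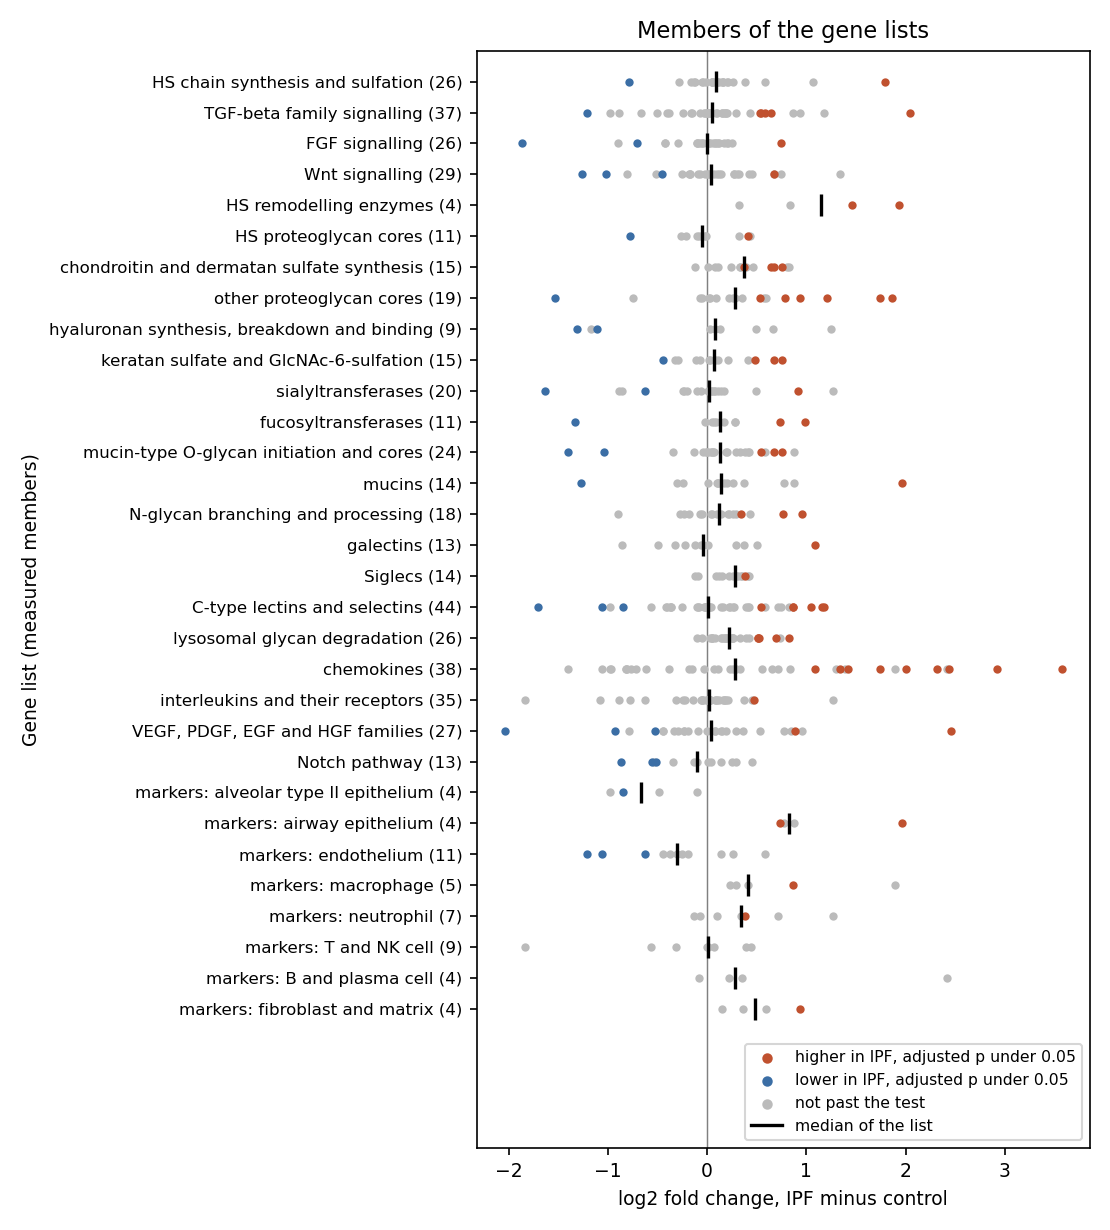
Log2 change between IPF and control (horizontal axis) of each measured member of the gene lists with at least 4 members (vertical axis, number measured in brackets), 1 point per gene and a bar at the median. Members past an adjusted p of 0.05 are coloured. The medians of chondroitin sulfate synthesis (0.37 as deposited, 0.02 with housekeeping centring) and lysosomal degradation (0.22 and -0.13) lie right of 0 as deposited. That of the endothelial markers (-0.30 and -0.65) lies left of it.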

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

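Every setting named here was chosen before the data were examined, except the counts of list members without control replicates 2 and 3, given with the results. SULF1 kept its direction and its call in each setting run for it (not the other thresholds or the test without moderation, run for the counts only), with log2 changes of 1.58 to 2.12. SULF2 kept its direction in the same settings. Background correction could not be varied, and without detection calls the signal over background limits what can be said of dim probe sets such as HS6ST2. Why each value below moved was not tested, except that leaving out an array leaves fewer samples.

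The fits without 1 array called 9 to 98 probe sets, 8 to 63 higher and 1 to 35 lower, the lowest without control replicate 3 and the highest without IPF replicate 3; 9 to 78 of these calls were among the 145. SULF2 was at 1.349 to 1.638 in these fits (adjusted p 0.0756 without control replicate 3 and 0.0521 without IPF replicate 2). The shift of the TGF-beta list, 0.002089, was -0.0334 to 0.06583, that of chondroitin sulfate synthesis 0.2504 to 0.3389, that of lysosomal degradation 0.1407 to 0.2191 and that of the endothelial markers -0.4848 to -0.3382. A threshold of 0.1 gave 244 calls, 161 higher and 83 lower. Asking also for 1.5-fold gave 96, 56 of them higher, and a test without moderation gave 18, 13 higher and 5 lower.

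Quantile normalization left 59 higher calls and median centring 43. Housekeeping centring, on genes that were themselves higher in IPF, gave 227 calls, 29 higher and 198 lower. It turned the sign of MUC13 (-0.09422), MAN1A2 (-0.01474), SIGLEC15 (-0.03894), SIGLEC5 (-0.01371) and CXCR5 (-0.1332). The TGF-beta shift turned to -0.003286 with quantile normalization and -0.008371 with the mean of a gene's probe sets, and the Wnt change is 0.03422 in fry, which does not set it against other genes. The chondroitin sulfate list lost its call with an intensity trend (0.2997, adjusted p 0.0616), quantile normalization (0.2787), without the dimmest 25% (0.2944) or 50% (0.2875), and with an estimated correlation (0.2997, adjusted p 0.659). The lysosomal list lost it with a trend (0.1802), quantile normalization (0.1741), housekeeping centring (0.1802, adjusted p 0.231), without the dimmest 25% (0.1826) or 50% (0.179), with an estimated correlation (0.1802) and in fry (0.2735, adjusted p 0.0505). The endothelial list lost it with quantile normalization (-0.4152), housekeeping centring (-0.4178), without the dimmest 50% (-0.5085) and with an estimated correlation (-0.4178, adjusted p 0.614).

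The fit with the replicate block called 45 probe sets, 26 higher and 19 lower, and 39 of the 145 were among them. Deviations of samples with the same number from their group means correlated at -0.11, 0.31 and 0.20 for replicates 1, 2 and 3. Control replicates 2 and 3 correlated best with the IPF replicate of the same number, and control replicate 1 did not. With 3 samples per group this cannot tell whether samples of equal number share more than the number. Of the named genes, 40 lost their call under the block.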

Other observations

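The share of higher calls, the endothelial marker test against matched lists, the matched-list tests of the 2 higher lists and the macrophage test were fixed before their results were seen; the test of whether endothelial markers moved by equal amounts was chosen after, with its repeats that leave out 1 marker, as were the genes named in this part.

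Among genes in none of the lists, 24 passed limma's test, 17 higher in IPF and 7 lower. None of the 24 passed without control replicate 3, and of the 6 fits that each left out 1 array, 10 genes passed in 0 and 10 in 1. IGFBP5 passed in 5 of these fits and SMO and TNFSF13B in 3; each other gene of the 24 named below passed in 0 or 1 by its brightest probe set. IGFBP5, a binding protein of the insulin-like growth factors, rose 3.16-fold (log2 change 1.66, SE 0.18, limma adjusted p = 0.0103), beside the rise of IGF1, and TNFSF13B (BAFF, a survival factor of B cells) rose 2.44-fold (limma adjusted p = 0.025). SMO, the signal transducer of the Hedgehog pathway, rose by 0.57 (SE 0.09). UGDH, which makes the UDP-glucuronic acid used for chondroitin sulfate, heparan sulfate and hyaluronan, rose by 0.74 (SE 0.17), and GFPT1 and GNPNAT1, early enzymes of UDP-GlcNAc synthesis, rose by 0.47 (SE 0.09) and 0.35 (SE 0.08). PAPSS2, which makes the sulfate donor PAPS, fell by 0.76 (SE 0.16, limma adjusted p = 0.0393), and PMM1, a phosphomannomutase, fell by 1.04 (SE 0.23, limma adjusted p = 0.0434). GM2A, the lysosomal activator of ganglioside breakdown, rose by 0.91 (SE 0.16), LIPA, lysosomal acid lipase, by 0.63 (SE 0.13) and CTBS, a lysosomal chitobiase, by 0.45 (SE 0.10). Housekeeping centring moves each of these log2 changes by -0.36, a shift as large as the rise of GNPNAT1. P3H1, a prolyl hydroxylase of collagen, rose by 0.50 (SE 0.10), and ILK, integrin-linked kinase, fell by 0.51 (SE 0.08) in its brightest probe set and by 0.72 in another.

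Some chemokines differed widely between the controls, while others, such as CCL11 (SD 0.25) and CXCL12 in its brightest probe set (SD 0.22), did not. Another probe set of CXCL12 had a control SD of 0.72 and its remaining probe set 0.26. Control replicate 2 had the highest control values of CXCL1 (9.59), CXCL3 (9.61), CCL20 (8.95) and CXCL8 (10.07), against 5.46 to 7.49 for these genes in the other controls, and the lowest of the platelet chemokine PPBP (4.63, against at least 8.64). It was also lowest for the interferon-induced CXCL9 (6.94, against 9.86 and 8.03), CXCL10 (6.18, against 8.43 and 7.63) and CXCL11 (4.18, against 6.97 and 5.86) and for the macrophage chemokine CCL18 (7.76, against 10.27 and 10.38). None of these 9 passed limma's test between groups (adjusted p of 0.145 to 0.929). In IPF the spread was wide for CXCL13, at 8.45, 5.79 and 5.61, against 3.88 to 4.71 in the controls, and for SFRP1, a secreted Wnt antagonist, at 9.48, 6.16 and 8.03, against 6.15 to 6.85. No biological explanation of these differences between lungs was tested.

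The count of 145 probe sets was set against other splits of the 6 arrays. Of the 10 splits into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 2; with 10 splits no share under 0.05 is possible. More probe sets were higher than lower, 64.1% of the calls, and with each array centred on its median 37.39% were, with an exact 95% interval of 28.55 to 46.9. That centring moves the median log2 change by -0.14 and so lowers the share whatever its cause. Whether the excess comes from a technical offset between the arrays of the 2 groups, or from more of the array's genes being higher in IPF lungs, stays open.

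The endothelial markers were lower in IPF (median log2 change -0.30), a call lost with an estimated correlation (camera adjusted p 0.614) and with housekeeping centring (0.231). With that centring, which takes the same amount from every gene, their median was -0.65 and the list's shift stayed at -0.42. A fall shared by probe sets of the markers' brightness is argued against, as 0.33% of 10000 random lists matched on mean expression had a median as low, the central 95% of them lying between -0.13 and 0.34. The marker list had already passed camera, so this share bears on brightness only. An equal change of all 11 markers is argued against by their spread, from -1.21 for ACVRL1 (SE 0.21) to 0.26 for SELP (SE 0.17). This leaves aside SELE, whose 0.59 has an SE of 1.21 and weighs little. Equal changes gave a spread as wide in a fraction of 0.0047 of the simulated draws, and of 0.0035 to 0.0131 with each marker left out in turn, though the simulation treats the markers as independent. A smaller share of endothelial cells would lower all markers equally only if no other cells made them. That was not tested, so the spread cannot decide on a smaller share. A smaller share, alone or together with changes inside these cells, may still hold, and a difference in disease is the contrast that the design names.

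The chondroitin sulfate and lysosomal lists were higher in IPF as deposited, but both calls were lost with an estimated correlation (camera adjusted p 0.659 for each), and their medians were 0.02 and -0.13 with housekeeping centring, which takes the same amount from every gene; there the chondroitin sulfate list kept its call (camera adjusted p 0.00557) and the lysosomal list lost it (0.231). A rise shared by all probe sets of their brightness is argued against, as 1.01% and 2.28% of matched random lists had medians as high. Both lists had already passed camera, and random lists do not keep the correlation between members of a list. These shares therefore bear on brightness only and are no further evidence that the lists moved. More macrophages, which are rich in lysosomes, could account for the lysosomal rise. With the mean of the macrophage markers as a covariate the IPF coefficient of the lysosomal list was 0.183, against 0.27 without it, with a 95% interval of -0.22 to 0.59, so 6 arrays are too few to decide. For the chondroitin sulfate list more fibroblasts stay open as a cause, since all 4 measured fibroblast markers had a positive log2 change too (median 0.48 as deposited, 0.13 with housekeeping centring).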
